A study of Mus musculus with 3 samples.

How the data were processed

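Visium spatial expression was measured in 3 libraries of mouse distal colon, WT intact, WT wound at day 2 and KO wound at day 2. Per the labels' protocols, sections of 10 µm were cut from fresh-frozen tissue and 3 biological replicates shared each library. The labels tie no spot to an animal, so each library was treated as 1 sample. All libraries came from 1 slide and each from its own capture area, so area and group cannot be told apart. Per the file headers, the authors made the matrices with Space Ranger 1.2.1, and per the submitters' processing notes the genome build was mm10. The deposited matrices hold raw UMI counts for 32285 features on the spots over tissue, and the deposited position tables give the place of each of 4992 spots on the array. The aligner, the annotation release and the read filters were not given in the sources used here. The histology images were not used. Neighbouring genes and gene spans came from a RefSeq table of the GRCm38 assembly.

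UMIs were summed over all spots of a library and scaled to the library total as CPM. The total was 8180099 in WT intact, 11306771 in WT wound and 8930574 in KO wound, so that 3 UMIs, the floor used for genes with a count of 0, were 0.367, 0.265 and 0.336 CPM. Ratios between libraries, for WT wound over WT intact and for KO wound over WT wound, have exact conditional binomial intervals at 95%, and shares of spots have exact Clopper-Pearson intervals. These intervals and floors cover counting error only. No test between groups and no p-value was possible with 1 library per group. Mitochondrial genes held 5.36%, 5.60% and 4.26% of UMIs in WT intact, WT wound and KO wound. The median log2 ratio of all genes was 0.09 for WT wound over WT intact and 0.05 for KO over WT wound.

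Genes with at least 50 UMIs over both libraries were compared, and a ratio of at least 2 or at most 0.5 counted as changed. The comparisons, the thresholds, the 35 gene lists and the rule for naming genes were fixed before the data were examined. The named genes were, per comparison, up to 10 in each direction with at least 200 UMIs, ranked by the interval bound nearest to 1, without mitochondrial, ribosomal-protein, immunoglobulin variable-segment and unnamed genes. Up to 3 genes in each direction per shared region, up to 2 in each direction per list and all genes of the HGF pathway were named by the same ranking, and a selection of these is given. Genes of the closing section outside this rule were chosen after their values were seen. The median log2 ratio of the members of a list with at least 10 UMIs was ranked among 10000 random lists of the same size, matched in 20 expression bins. A median above percentile 97.5 counted as above random lists and one below percentile 2.5 as below.

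Tissue pieces were connected groups of at least 20 neighbouring spots. Each library had 3, with 116, 148 and 233 spots in WT intact, 251, 176 and 213 in WT wound and 212, 199 and 158 in KO wound, and 5 WT intact and 3 KO spots lay outside them. The labels tie no piece to an animal, so pieces are given as ranges. By chance 3 pieces lie wholly apart from another 3 in 10% of genes, or 5% per direction. Apart pieces were seen for 22.5% of all genes in WT wound over WT intact and 8.03% in KO over WT wound.

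Regions were Leiden clusters of all spots of the 3 libraries (leidenalg 0.10.2, igraph 0.11.9), from log-scaled counts of 2000 variable genes, 20 principal components, 15 neighbours and a resolution of 0.5. Most gene lists, 308 genes in all, were left out of the clustering. A region was compared where each library had at least 20 spots in it, and the region-standardised ratio was the mean log2 ratio over such regions with equal weights and a pseudocount of 0.5. Neutrophil-rich spots were counted after each spot was thinned to 1000 UMIs. Profiles ran over rings of array distance from the 10% of spots highest in neutrophil genes and, chosen after the data were seen, from a region of the clustering centred per library.

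The ratio method was tested on simulated data drawn from the real libraries' means and totals. Only counting error was simulated, the error that the intervals assume, so coverage near 95% was built in. The simulation checks the computation and says nothing about the spread between pieces or animals. For WT wound over WT intact, run on 12402 genes, 50 of 50 genes simulated with a 4-fold rise and 50 of 50 with a 0.25-fold ratio were called. Of the genes simulated with a 2-fold rise, at the threshold itself, 27 of 50 were called, and intervals held the true ratio of 95.3% of unchanged genes. For KO over WT wound, run on 12463 genes, 50 of 50 with a 4-fold rise, 50 of 50 with a 0.25-fold ratio and 24 of 50 with a 2-fold rise were called, and the coverage was 95.9%. The alternatives tried were other library scalings (edgeR 4.0.16 for TMM factors only), other gene totals, equal weight per spot, minimum UMIs, thinning, a pseudocount, other list statistics, region settings, core definitions and each tissue piece left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.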

Results

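Spatial gene expression was measured in sections of mouse distal colon with Visium, an assay in which a tissue section lies on an array of barcoded spots and each captured polyadenylated transcript is counted by a unique molecular identifier (UMI). There were 3 libraries, 1 per group: wild-type (WT) intact colon, WT colon at day 2 after wounding, and colon at day 2 after wounding from mice labelled as knockout (KO) for Hgfac. Hgfac encodes HGF activator, a serine protease that converts the precursor of hepatocyte growth factor (HGF) to its active form. Each library pooled 3 biological replicates, and the spots of each section formed 3 separate pieces of tissue. KO intact colon was not analysed here. The WT intact library held 502 spots and 8180099 UMIs, the WT wound library 640 spots and 11306771 UMIs, and the KO wound library 572 spots and 8930574 UMIs. The median depth was 11416 UMIs per spot in WT intact, 14638 in WT wound and 13168 in KO wound. With 1 library per group there was no replicate error and no test was made between groups. Brackets give 95% intervals of the counting error, except for medians over genes in the closing section, whose brackets come from resampling the genes. Ranges over the 3 pieces of a library show the spread within it. Among genes with at least 50 UMIs over both libraries, those with a ratio of at least 2 or at most 0.5 were counted as changed.

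The first question was how Hgfac itself was counted. Hgfac (ENSMUSG00000029102; GRCm38 chromosome 5, 35041509 to 35048461) had 627 UMIs in WT intact, 1072 in WT wound and 438 in KO wound, or 76.6, 94.8 and 49.0 CPM, the count of a gene scaled to the total of its library. The library labelled KO therefore held 0.517 times the WT wound level [0.462 to 0.579], and its 3 pieces, at 38.4 to 59.5 CPM, lay below the WT wound pieces, at 87.6 to 105. Hgfac UMIs were found on 282, 428 and 261 spots of the 3 libraries. Regions were split by whether UMIs of the epithelial list exceeded those of the smooth-muscle list. In WT wound Hgfac reached 110 CPM where they did and 62.5 in the other regions, and in KO wound 60.6 and 23.9. The other regions were not muscle alone, since those led by Cartpt and by Car3 were among them. The region led by S100a9, Cxcl5 and Lox held 135 of their 313 WT wound spots and 177 of their 254 KO spots. The 62.5 and 23.9 therefore compare different mixes of tissue. Within regions shared by both wound libraries the ratio was 0.382 [0.256 to 0.46]. The part of the gene that was deleted and the positions of the UMIs along the transcript are not known, so these counts check the label only in part.

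**Figure D1:**
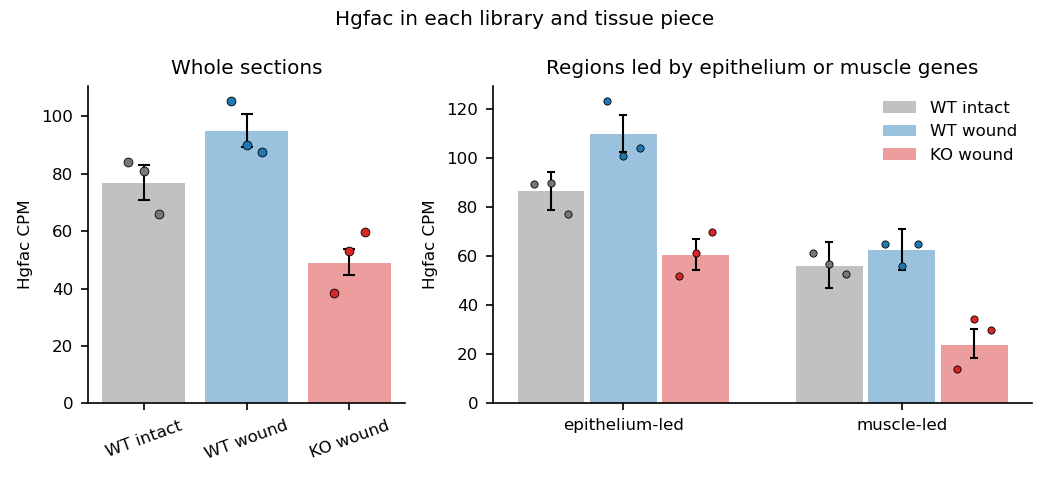
Hgfac in the 3 libraries, in CPM, for whole sections and for spots led by epithelial or muscle genes (bars, libraries with 95% counting intervals, and points, tissue pieces). Over whole sections the KO wound pieces lay at 38.4 to 59.5, below the WT wound pieces at 87.6 to 105.

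The other genes of the HGF pathway were then compared. Met, the HGF receptor, had 199, 304 and 277 UMIs in WT intact, WT wound and KO wound, and Hgf itself had 18, 15 and 27, too few for a map. Of the 27 Hgf UMIs in KO wound, 18 lay in piece 3, at 6.66 CPM, while the other KO pieces, at 1.14 and 1.68, lay close to the WT wound pieces, at 1.22 to 1.58. Mst1r, the receptor of the related macrophage-stimulating protein, was 1.29 times higher in WT wound than in WT intact [1.10 to 1.53], and 1.21 times higher again in KO wound [1.05 to 1.39], although over regions shared by the wound libraries the KO ratio was 0.982. Spint1, an inhibitor of HGF activator, was 1.28 times higher in WT wound than in intact colon [1.2 to 1.37]. Its KO over WT wound ratio of 1.13 [1.06 to 1.19] fell to 0.887 over shared regions. Plaur, the urokinase receptor, was 1.52 times higher in WT wound than in intact colon [1.10 to 2.13] and 2.52 times higher in KO than in WT wound [2.02 to 3.17], with the pieces apart. Hpn, which encodes hepsin, another protease that activates pro-HGF, was lower in WT wound, at 0.629 times the intact level [0.460 to 0.858].

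The WT wound library was compared with WT intact colon to describe the wound response at day 2. Inflammatory genes were higher in the wound. The acute-phase gene Serpina3n was 9.62 times the intact level [7.71 to 12.1] and the monocyte chemokine receptor Ccr2 7.04 times [5.01 to 10.2]. Arg1, an enzyme of wound macrophages, was 21.9 times higher [7.28 to 108] over 3 intact UMIs, and 13.4 to 48.6 times with any 1 piece left out. The neutrophil genes S100a9 and S100a8 were 16.2 times [5.30 to 80.3] and 11.8 times [3.81 to 59.3] higher, also over few intact UMIs. All 3 intact S100a9 UMIs lay in WT intact piece 3, so no ratio could be had without it, and S100a9 was 9.83 times higher without WT intact piece 2. S100a8 was 23.2 times higher without WT intact piece 3. Il1b was 8.06 times higher [3.73 to 20.7], but 2.30 times without WT wound piece 3. Cd74, the invariant chain of MHC class II, was 2.10 times higher [2.01 to 2.20], and the complement gene C4b 2.55 times [2.27 to 2.86]. The T-cell chemokine gene Ccl5 was 7.69 times higher [5.05 to 12.2], and 17.0 times without WT intact piece 1. The antibody gene Ighg2b was 206 times higher [56.8 to 1707] over 2 intact UMIs, both in WT intact piece 1, and 31.2 times without WT wound piece 1. Without that intact piece its intact count was 0.

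Matrix genes rose with them. All 16 collagen and matrix genes had higher ratios, with Col1a1 at 3.28 [3.12 to 3.46], and their summed UMIs were 1.99 times the intact level [1.96 to 2.02]. The collagen cross-linking enzyme Lox was 7.20 times higher [4.73 to 11.5] and the protease inhibitor Timp1 6.85 times [5.21 to 9.17]. Clu, which regenerating epithelium and other cells express, was 6.81 times higher over the whole library [6.06 to 7.68]. It was at 0.588 times in the 1 region shared by both libraries without centring, led by Cartpt and Vip. In 1 of the 3 shared regions of the clustering centred per library it was 9.59 times higher [7.32 to 12.8], with the pieces apart. The goblet-cell genes Muc2 and Retnlb were 1.81 times [1.76 to 1.86] and 21.1 times [10.9 to 46.6] higher, the latter 13.8 to 115 times with any 1 piece left out. Clca4b, a chloride-channel regulator of the surface epithelium, was 29.1 times higher [17.2 to 53.6], and 62.0 times without WT intact piece 2. Scnn1g, a subunit of the epithelial sodium channel, was 7.14 times higher [5.23 to 9.97], and 4.64 times without WT wound piece 2. Cyp2c55, an enzyme of surface colonocytes, fell to 0.275 times the intact level [0.257 to 0.294].

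Genes of nerve, muscle and dividing cells were lower in the WT wound. The hormone gene Sst was at 0.0922 times the intact level [0.0718 to 0.117], the enteric neuropeptide gene Vip at 0.285 [0.266 to 0.306] and the synaptic gene Snap25 at 0.339 [0.279 to 0.411]. Npy was at 0.0849 [0.0513 to 0.134], and at 0.181 without WT intact piece 3. The muscle genes Smtn and Tagln were at 0.101 [0.0896 to 0.113] and 0.532 [0.522 to 0.543]. Smtn was the only 1 of the 10 smooth-muscle genes at or below 0.5, so it does not stand for muscle. It was about as low in each of the 3 shared regions of the clustering centred per library, at 0.093, 0.109 and 0.124. The chromatin gene Hmgb2 was at 0.512 [0.474 to 0.552], and the mitotic gene Birc5 at 0.469 [0.406 to 0.541], or 0.763 without WT intact piece 2. The mitochondrial genes Cox8a and Ndufaf8 were at 0.187 [0.182 to 0.192] and 0.159 [0.140 to 0.180], and the histone gene Hist1h4h at 0.0512 [0.0316 to 0.0789]. The capture area differed between the WT intact and WT wound libraries, so its effect on such genes cannot be told apart from wounding. Genes low in both wound libraries, such as Cox8a, are taken up in the closing section.

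Of 12402 genes compared between WT wound and WT intact, 408 were higher and 382 lower, where counting noise alone gave a mean of 6.90 and 3.58. The 3 WT wound pieces all lay above the intact pieces for 322 of the higher genes and all below for 246 of the lower ones. Those genes were selected on the same pieces, so no chance level applies to them. Over all genes the pieces were apart for 22.5%, where chance gives 10%. Of 33 lists of genes, 17 had a median ratio above matched random lists and 6 below. In log2 units the median was 1.61 for cytokines and chemokines, 1.06 for macrophage genes, 1.06 for MHC class II genes, 0.90 for complement genes and 0.49 for hypoxia genes. The hypoxia genes had overlapping pieces. They lay within random lists in the shared region and in all 3 shared regions of the clustering centred per library. For interferon-response genes the median was 0.66, but -0.01 over the shared region. With centring per library they lay above random lists in 2 of the 3 shared regions. The neutrophil list had a median of 2.86, yet its summed UMIs were only 1.04 times the intact level, with overlapping pieces, and they were 0.431 times that level [0.23 to 0.713] within the shared region and 0.558 times [0.419 to 0.711] within shared regions of the clustering centred per library. Early ERK and receptor-kinase response genes had a median of 0.36, above random lists in only 3 of 6 cases with 1 piece left out. The median was -1.11 for enteric nervous genes. These lay below random lists in each of the 3 shared regions of the clustering centred per library, at -0.53, -0.24 and -0.38, although the median of their mean ratio over those regions was 0.02. It was -0.53 for cell-cycle genes, 0.01 without WT intact piece 2 and 0.09 over the shared region. It was -0.43 for smooth-muscle genes, 0.06 without WT intact piece 3. The lists of epithelial and stem-cell genes lay within the random range, at 0.07 and 0.14.

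**Figure D2:**
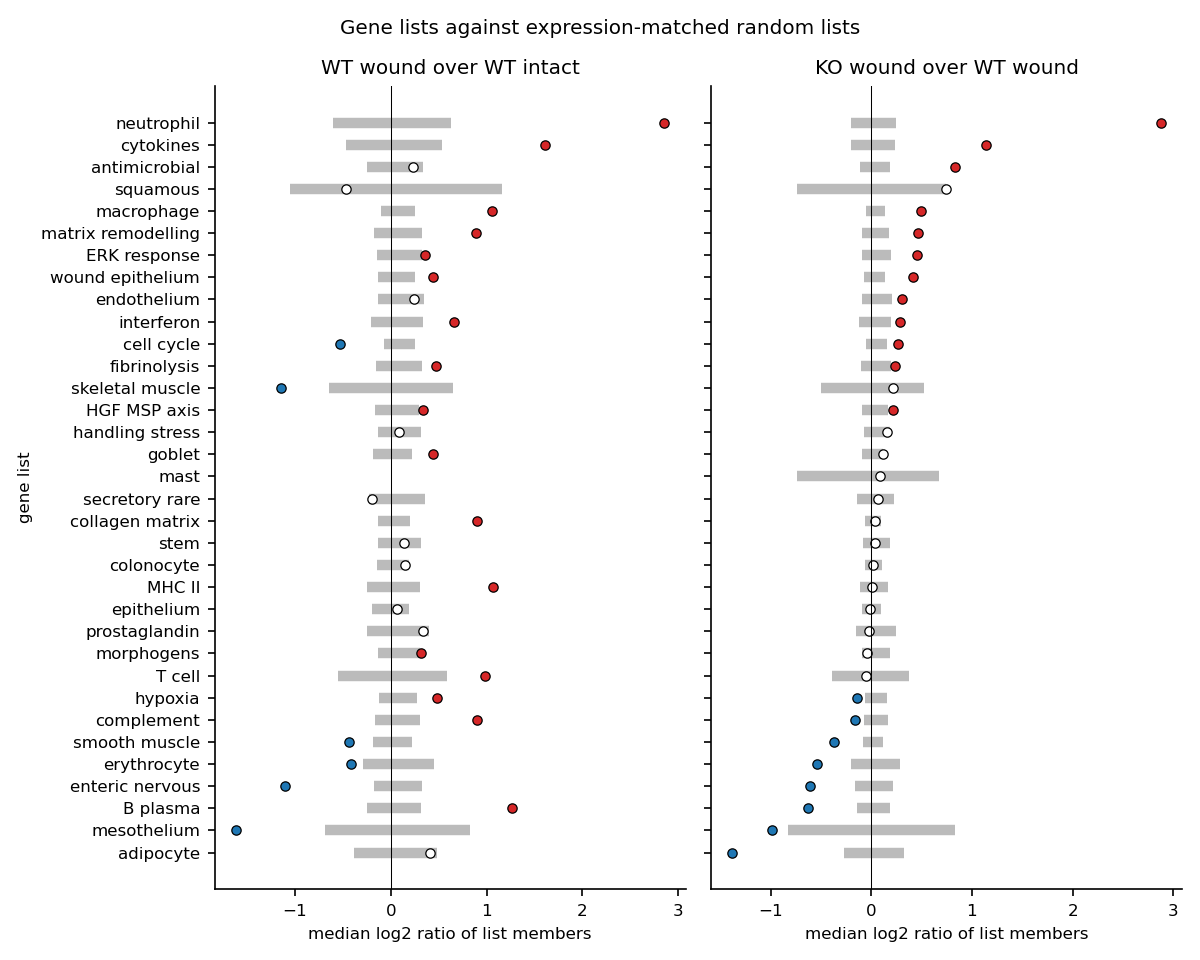
Median log2 ratio of each gene list for WT wound over WT intact and for KO wound over WT wound, with grey bars for the central 95% of random lists and red, blue and white points above, below and within it. The neutrophil list had the highest median in both comparisons, 2.86 and 2.87.

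Grouping of spots by expression, without centring per library, separated the intact from the wound sections. The regions led by Smtn (after Kap, nearly all from 1 stray KO spot), by Epb41l4aos and Cenpa, and by Cyp2c55 and S100g held 206, 140 and 56 WT intact spots and at most 1 spot of each wound library. Only the region led by Cartpt, Bglap, Gal and Vip, with 78 WT intact and 28 WT wound spots, allowed a comparison within a region in this grouping, whereas centring per library gave 3 shared regions. There Col1a1 was 2.66 times higher in WT wound, the matrix genes Fn1 and Mgp 2.44 and 2.51 times, while Sst was at 0.017 and Pcsk1n, a gene of neuroendocrine cells, at 0.159 times the intact level. The pieces overlapped for Fn1, at 990.5 to 4849 CPM in WT wound and 970.0 to 1218 in intact colon, and for Mgp, and these ratios were not repeated with single pieces left out. Apart from the values given within shared regions, WT wound ratios compared whole sections, so differences in tissue content were not removed from them. The region led by Cartpt and the 3 regions shared with centring all held more UMIs of the smooth-muscle list than of the epithelial list. Epithelium-led tissue was therefore not compared within a region for WT wound over WT intact.

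**Figure D3:**
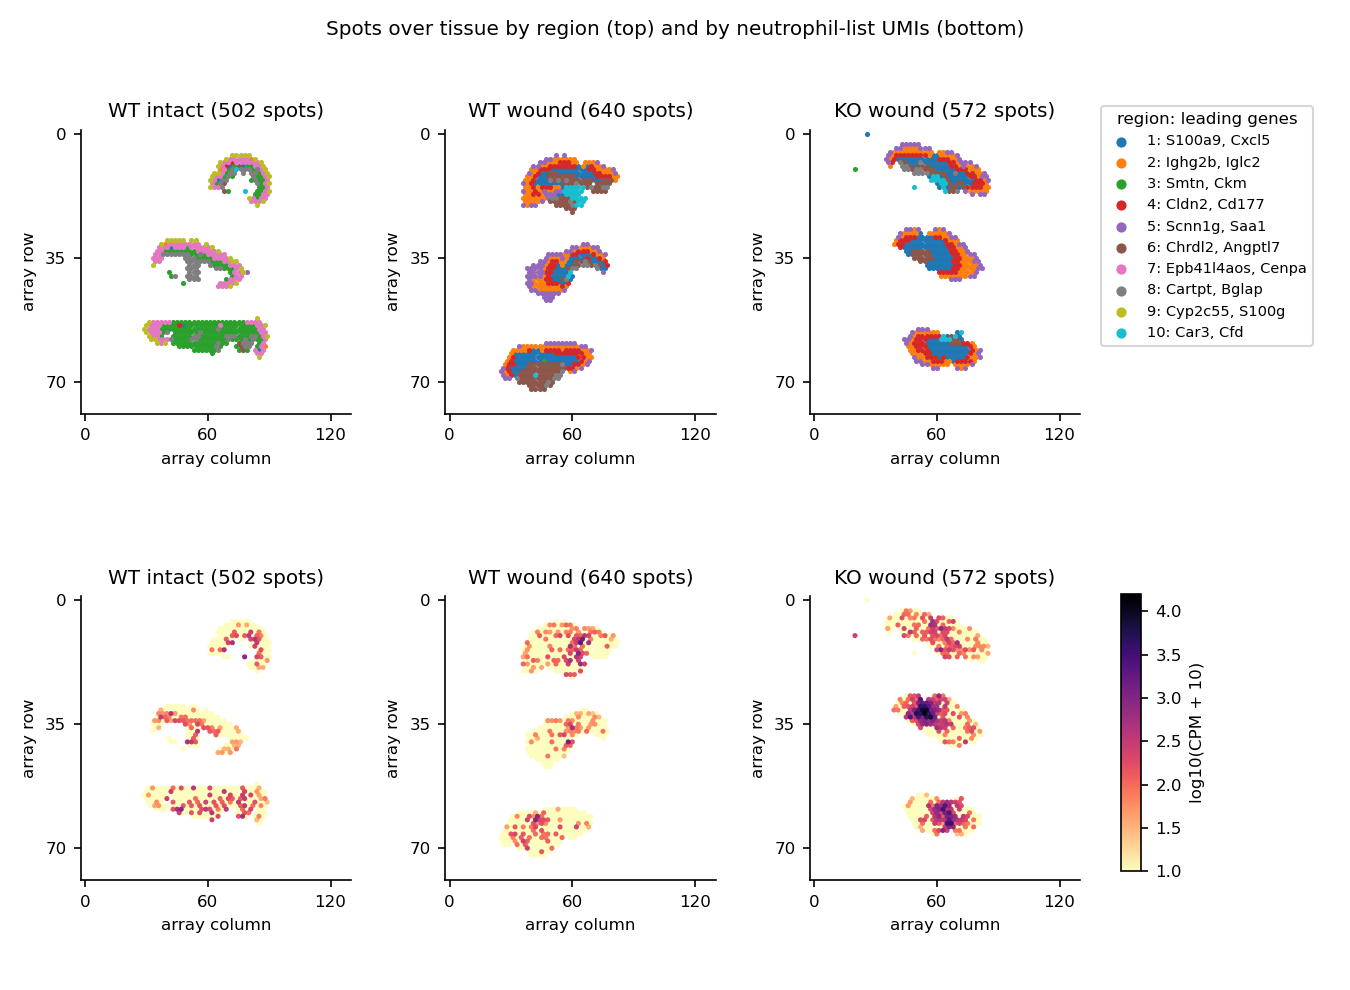
Position of every spot on the array in each library, coloured by region of similar expression (top) and by log10 CPM of the neutrophil list (bottom). WT intact spots and wound spots fell mostly in different regions.

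The KO wound library was compared with the WT wound library to ask how the wound response differed when Hgfac was targeted. Neutrophil and inflammatory genes were higher in the library labelled KO. S100a8, a calcium-binding protein abundant in neutrophils, was 16.1 times the WT level [12.1 to 22.1], and its pieces ranged from 9.81 to 150 CPM against 1.97 to 6.11 in WT. It was 8.40 times higher without KO piece 2 and 25.4 times without KO piece 1. S100a9 was 14.8 times higher [11.5 to 19.3], and 8.05 times and 23.1 times without the same pieces. Cxcl5, a neutrophil-attracting chemokine, was 9.05 times higher [7.36 to 11.2] with overlapping pieces, and 3.21 times without KO piece 2 and 14.3 times without KO piece 1. Il1b was 5.11 times higher [3.98 to 6.64], and 18 times without WT wound piece 3. Cxcl2 had 53 UMIs in KO and 0 in WT wound, at least 22.4-fold higher against a floor of 3 counts. Selp, the adhesion molecule P-selectin, was 14.4 times higher [8.90 to 24.8], and 3.53 times without KO piece 3.

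Several macrophage and matrix-remodelling genes went the same way. Spp1, which encodes osteopontin, was 3.60 times higher [2.98 to 4.36] and 7.53 times without WT wound piece 1. Arg1 was 3.26 times higher [2.55 to 4.19], and 5.26 times without KO piece 1. Mmp9, a gelatinase of neutrophils and macrophages, was 4.29 times higher [3.18 to 5.87], and 9.74 times without WT wound piece 1. Thbs1, a matrix protein that activates TGF-beta, was 2.30 times higher [2.03 to 2.60], with the pieces apart. Grem1, a BMP antagonist of the stroma, was 1.7 times higher [1.56 to 1.85]. The interferon regulator Irf7 was 1.90 times higher [1.7 to 2.11] and the replication genes Rrm2 and Mcm5 2.23 times [1.82 to 2.74] and 1.69 times [1.44 to 1.97], again with the pieces apart.

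Genes expressed in epithelium went both ways. Retnlb was 3.89 times higher in KO than in WT wound [3.38 to 4.49], 2.5 times without KO piece 3 and 5.94 times without KO piece 1. Duoxa2, which matures the oxidase of the colon surface, was 2.34 times higher [1.97 to 2.80], and 1.36 times without KO piece 2. Guca2a, which encodes the hormone guanylin, was 1.5 times higher [1.46 to 1.55], and 2.38 times without WT wound piece 2. Clu was at 0.638 times the WT level [0.599 to 0.679], the colonocyte enzyme Car1 at 0.566 [0.553 to 0.579] and the calcium-binding S100g at 0.519 [0.460 to 0.585]. Of the early ERK and receptor-kinase response genes, Phlda1 was 1.5 times higher [1.29 to 1.75] and Ier3 1.42 times [1.24 to 1.63].

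Other genes were lower in KO wound, and several of them depended on 1 piece. The antibody genes Iglc1 and Ighg2b were at 0.0684 times [0.0599 to 0.0778] and 0.107 times [0.0777 to 0.143] the WT level. Iglc1 was at 0.0347 without KO piece 3 and 0.238 without WT wound piece 2, and Ighg2b at 0.705 without WT wound piece 1. Iglc2 was at 0.184 [0.157 to 0.214] but 0.995 without WT wound piece 2, and the fat gene Cfd at 0.175 but 6.03 without WT wound piece 1 and 0.113 without WT wound piece 2. Nos1, the nitric oxide synthase of enteric neurons, was at 0.299 [0.201 to 0.435] with the pieces apart, and at 0.0285 without KO piece 1. Myh11, a smooth-muscle myosin, was at 0.702 [0.674 to 0.730], and at 0.381 without KO piece 1. Retnla, a resistin-like gene of alternatively activated macrophages, was 3.86 times higher in KO [3.32 to 4.50] but 0.130 times without KO piece 1.

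Of 12463 genes compared between the wound libraries, 91 were higher and 93 lower in KO, where counting noise alone gave a mean of 3.90 and 5.98. The KO pieces all lay above the WT pieces for 52 of the higher genes and all below for 23 of the lower ones, again after selection on the same pieces. Over all genes the pieces were apart for 8.03%, where chance gives 10%. The count of higher genes was 150 without WT wound piece 3. The count of lower genes was 54 without WT wound piece 1, 56 without KO piece 2, 145 without WT wound piece 2 and 295 without KO piece 1. Of 34 lists, 12 lay above matched random lists and 8 below, or 5 below without WT wound piece 3. The neutrophil list had a median log2 ratio of 2.87, a summed ratio of 7.65 [6.85 to 8.56] and pieces at 62.8 to 497 CPM against 23.9 to 43.0. Its summed ratio was 4.49 without KO piece 2, and its median stayed at 2.0 to 3.37 with any 1 piece left out. S100a8 and S100a9 held 625 and 785 of its 2235 UMIs in KO, and 49 and 67 of its 370 in WT wound. The summed ratio thus rested largely on these genes, although 8 of the 9 members with at least 50 UMIs were at least 2-fold higher. Cytokines and chemokines had a median of 1.14 and a summed ratio of 2.37 [2.22 to 2.53], matrix-remodelling genes 0.47 and 1.48 [1.43 to 1.54], and ERK-response genes 0.46 and 1.27 [1.2 to 1.34], each with the pieces apart. Among the 34 lists, 4 above random lists and 0 below had their pieces apart, near the 10% that chance gives. Apart pieces alone therefore do not set these lists off. Without KO piece 1 the median of ERK-response genes was 0.24, within the random range. Macrophage genes had a median of 0.50 with overlapping pieces, and 0.18 without KO piece 1, again within the random range. Within shared regions the summed ratio was 5.17 [4.41 to 6.21] for neutrophil genes, 2.22 [2.04 to 2.43] for cytokines and 1.22 [1.15 to 1.29] for ERK-response genes. By single region, neutrophil genes and cytokines each lay above random lists in 4 regions and within them in 1. ERK-response genes lay above in only 1 region and within in 4, or 1 and 5 with centring per library. Smooth-muscle genes had a median of -0.37, and all 10 were lower. With any 1 piece left out the median was -1.12, without KO piece 1, to -0.12. Their pieces overlapped, at 3543 to 10882 CPM in KO and 6638 to 10582 in WT wound. By single region they lay below random lists in 4 and within in 1. With centring per library they lay below in 2, within in 3 and above in 1. Enteric nervous genes had a median of -0.61, but 0.55 as the mean over shared regions, with all 4 single regions within the random range, and -2.02 without KO piece 1. With centring per library they lay above random lists in 3 single regions, within them in 2 and below in 0. The direction thus reversed in 2 of 18 alternatives. B-cell and plasma-cell genes had a median of -0.62, although their summed UMIs were 1.02 times the WT level, and -0.08 without WT wound piece 3. Collagen and matrix genes had a median of 0.04, within the random range, but -0.32 without KO piece 1, below it, and 0.15 to 0.16, above it, without WT wound piece 1, KO piece 2 or KO piece 3. The lists of stem-cell and T-cell genes lay within the random range, at 0.04 and -0.06.

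**Figure D4:**
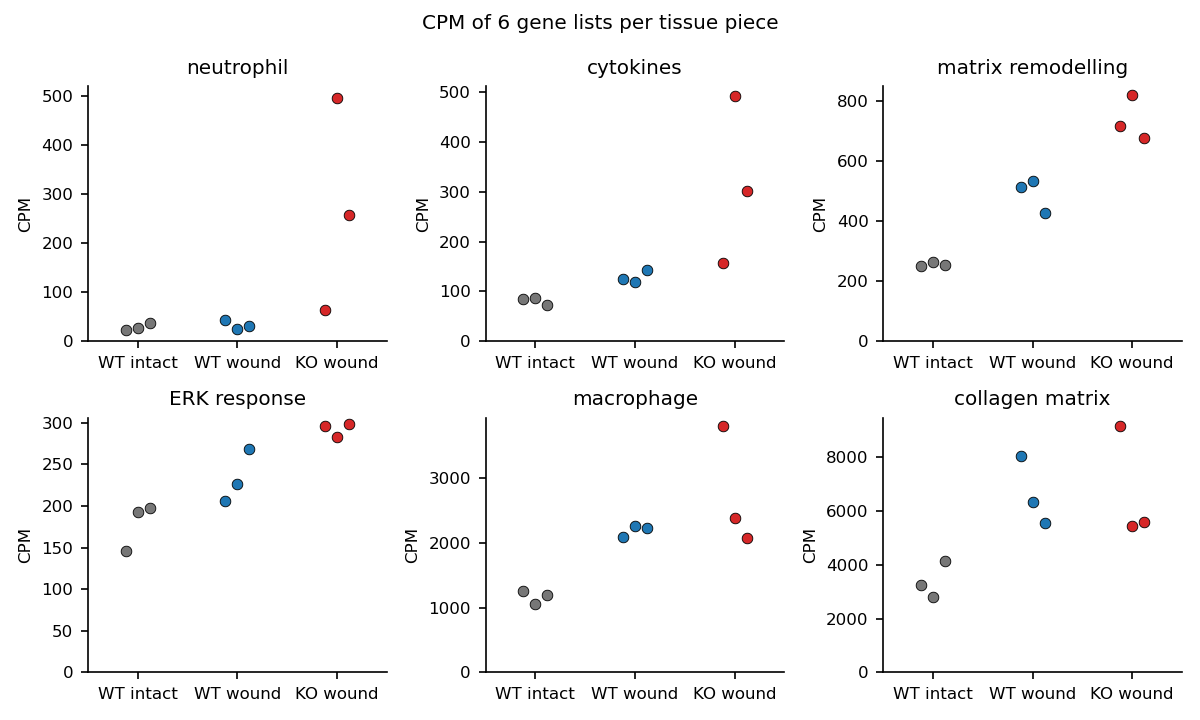
Summed CPM of 6 gene lists, with 1 point per tissue piece of the 3 libraries. For the neutrophil list the KO wound pieces lay at 62.8 to 497 and the WT wound pieces at 23.9 to 43.0.

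The wound libraries shared enough spots for comparisons within regions. In the region led by S100a9, Cxcl5 and Lox, with 135 WT and 177 KO spots, S100a8 was 13.4 times higher in KO [9.13 to 20.4], S100a9 11.8 times [8.64 to 16.4] and Cxcl5 11.0 times [8.16 to 15.2]. Without KO piece 2 these ratios were 6.01, 5.85 and 3.79, and without KO piece 1 they were 20.4, 17.7 and 16.7. In the region led by Ighg2b, Iglc2 and Plet1, Retnlb was 7.63 times higher [5.88 to 10.0], and 4.49 times without KO piece 3. In the region led by Cldn2, Cd177 and Reg4, the protease inhibitor Slpi was 3.2 times higher [2.39 to 4.34]. In the region led by Scnn1g and Saa1, Ly6m was 3.39 times higher [3.08 to 3.73] and Duoxa2 3.85 times [2.90 to 5.17], the latter 1.82 times without KO piece 2. Clu was there at 0.288 times the WT level [0.218 to 0.376], and at 0.791 without WT wound piece 2. In the region led by Chrdl2 and Angptl7, Timp1 was 3.59 times higher [2.92 to 4.44], 2.01 times without KO piece 2 and 5.74 times without KO piece 1, and Car1 was at 0.232 [0.168 to 0.314].

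Profiles were also drawn by distance from a region chosen after the data were seen. Plet1 marks epithelium at colonic wound edges, and with the clustering centred per library the region led by Arg1, Spp1, Plet1, Cxcl5 and Krt14 held 2 WT intact, 51 WT wound and 88 KO wound spots. The next leading genes were S100a8 and S100a9. These neutrophil genes, and Arg1, Spp1 and Cxcl5, were left out of the clustering. The region was still chosen after its leading genes were seen. High neutrophil, cytokine and macrophage values there therefore partly restate that choice. Neutrophil genes fell with distance from this region in both wound libraries, from 120 to 13.7 CPM in WT and from 1157 to 21.3 in KO at 5 or more array steps. The ratio of this region to those far spots was 8.71 in WT and 54.3 in KO for neutrophil genes, 4.32 and 10.8 for cytokines, and 2.65 and 5.68 for macrophage genes. By piece these ratios overlapped between the libraries, at 7.99 to 22.3 in WT and 17.0 to 84.2 in KO for neutrophil genes, 2.88 to 6.45 and 3.12 to 23.3 for cytokines, and 1.71 to 4.51 and 2.56 to 9.14 for macrophage genes. The ratio was 2.04 and 3.54 for ERK-response genes and 0.278 and 0.142 for colonocyte genes. For smooth-muscle genes the ratio was 0.761 in WT and 10.4 in KO, with overlapping pieces at 0.081 to 15.2 and 3.95 to 21.0. The tissue compared thus differed among pieces as well as between the library sums, and the WT and KO ratios were not like for like. Plaur fell from 47.9 to 5.08 CPM in WT and from 109 to 7.47 in KO. Hgfac went the opposite way, from 70.9 to 104 in WT and from 41.0 to 59.4 in KO. These profiles were not repeated with single pieces left out.

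**Figure D5:**
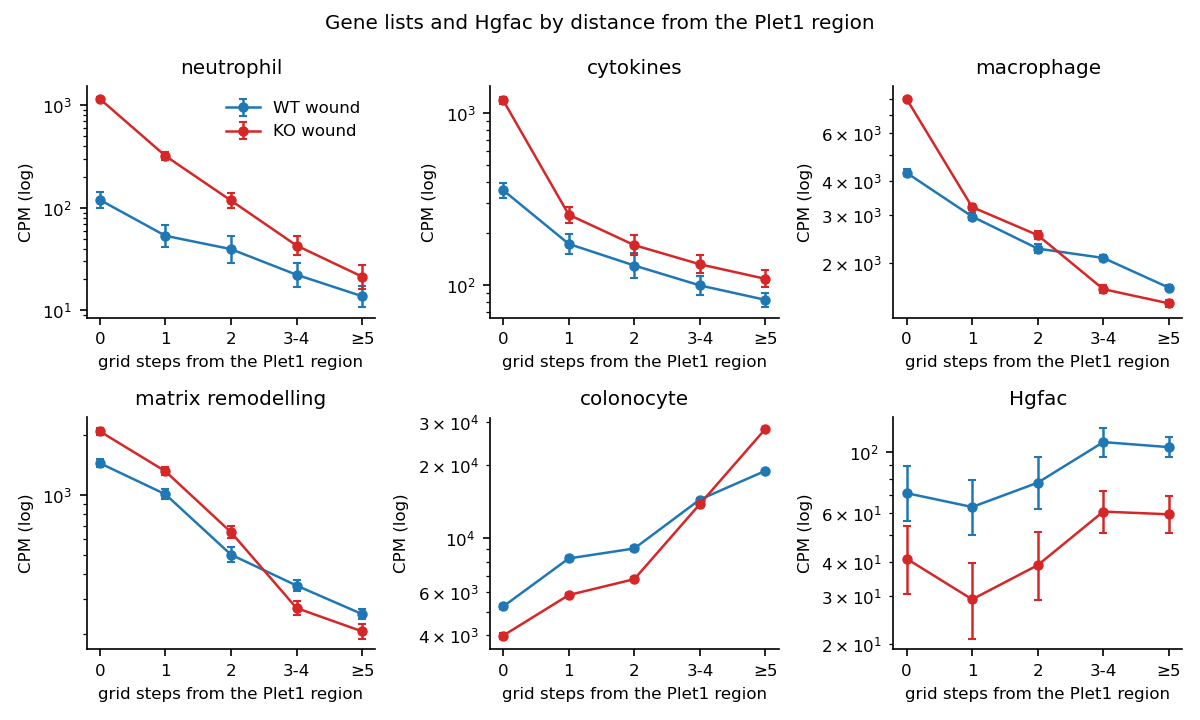
CPM of gene lists and of Hgfac by distance in array steps from the region led by Arg1, Spp1 and Plet1 in the wound libraries, on a log axis with 95% counting intervals. Neutrophil genes fell from 1157 to 21.3 in KO wound and from 120 to 13.7 in WT wound, though S100a8 and S100a9 were among the leading genes of that region.

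Spots rich in neutrophil transcripts, with at least 0.5% of their UMIs from the neutrophil list after every spot was thinned to 1000 UMIs, numbered 7 of 572 in KO wound, or 1.22% [0.493 to 2.51, exact binomial]. KO piece 2 held 6 of them, and without it the share was 0.268%. With S100a8 and S100a9 left out of the list the share was 0%. There were 0 of 639 in WT wound, which allows a share of up to 0.469% by the limit of 3 counts, and 0 of 499 in WT intact, which allows up to 0.601%. By the exact two-sided interval used for KO the upper bounds were 0.576% and 0.737%, above the lower KO bound. Spots with 0.2% to 1% numbered 28 in KO and 3 in WT wound. The 10% of spots highest in neutrophil genes made a core of 64 spots in WT wound, where the median was only 2 UMIs of the list per spot, and of 57 spots in KO wound, where it was 13. Of the 64 WT core spots, 40 had fewer than 3 such UMIs. Collagen genes were 6.71 times higher in the WT core than at 5 or more steps and 3.02 times in the KO core, and cytokines 1.84 and 15.1 times. By piece these overlapped, at 2.73 to 10.5 and 3.11 to 5.94 for collagen and 2.28 to 4.71 and 2.41 to 22.5 for cytokines. Smooth-muscle genes were at 5.85 in WT and 1.86 in KO, and fat genes at 13.7 and 1.87. The WT and KO cores thus differed in tissue, and their ratios were not like for like. The collagen ratios were 3.87 without WT wound piece 2 and 4.87 without KO piece 1, and the KO cytokine ratio was 7.48 without KO piece 2.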

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

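All tests on Hgfac in the library labelled KO and on the neutrophil genes in KO wound were chosen after the results were seen, and those on the genes low in both wound libraries before.

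Kap, an androgen-regulated gene of kidney proximal tubule, had 821 UMIs in the KO wound library and 0 in both WT libraries. Of these, 811 lay on 1 spot outside the 3 KO pieces, in data that the comparisons of pieces did not use, and 10 lay in the KO pieces.

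Neutrophil and cytokine genes were higher in KO than in WT wound, with S100a8 at 16.1 times the WT level. A larger number of KO spots in the region led by Arg1, Spp1 and Plet1 was argued against as the whole cause. Within that region the neutrophil ratio was still 9.67 [8.08 to 11.7] and the cytokine ratio 3.32 [2.97 to 3.72]. Without KO piece 2 these ratios were 4.95 [4.07 to 6.04] and 2.02 [1.78 to 2.30]. KO piece 1, at 196 CPM of neutrophil genes there, was little above the WT pieces at 83.1 to 156. Spots of the region may hold different amounts of wound tissue in WT and KO. More wound tissue within those KO spots therefore stays open. A single KO piece was argued against too, since without KO piece 2 the neutrophil ratio over whole sections was 4.49 [3.98 to 5.08] and the cytokine ratio 1.73 [1.61 to 1.87]. Blood as the whole cause was argued against, because haemoglobin genes had a ratio of 0.788 [0.74 to 0.839], at most 2.48 [2.25 to 2.73] without WT wound piece 3 and 3.08 [2.60 to 3.65] within that region, where KO piece 2 had 2447 CPM of neutrophil genes but 10.3 of haemoglobin genes. In KO piece 3 the region held 1423 CPM of haemoglobin genes, against 24.6 to 304 in the WT pieces, so blood may have added to that piece. A stronger neutrophil response where Hgfac was targeted may be an explanation, but the capture area differed with the genotype and stays open, as does a KO difference present before wounding, since there was no KO intact library.

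Hgfac UMIs numbered 438 in the library labelled KO, at 0.517 times the WT wound level. A WT piece among the KO pieces was argued against, because the highest KO piece had 59.5 CPM and the lowest 38.4, while the lowest WT wound piece had 87.6. Reads of the WT library as the whole source were argued against, because they would hold every ratio at or above that of Hgfac, and 8 of 9173 genes, such as Iglc1 at 0.0684, had intervals wholly below it, 6 of them after correction for the number of genes. A transcript of the targeted allele that keeps its 3' end is a candidate explanation, which stays open because the count table gives no position within the gene.

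Of 12402 genes, 321 were at most 0.5 times the intact level in both wound libraries, among them the ribosomal gene Rpl13 at 0.315 in WT and 0.293 in KO wound and the mitochondrial gene Cox8a at 0.187 and 0.168. All 6 wound pieces lay below all 3 intact pieces for 198 of them. A local wound response as the whole cause was argued against, because in spots 5 or more steps from the region led by Arg1 and Plet1 the median log2 ratio was -1.71, further from 0 than the -1.42 of all spots, and the median difference per gene was -0.18 [-0.23 to -0.13], away from 0. That bracket came from resampling the genes as if independent and does not cover counting error or the spread between animals. The far spots were not matched by tissue to the intact spots, and colonocyte genes in that region were at only 0.278 times the far level. These spots also entered the choice of the genes. The shift thus mixes tissue content and selection with distance. A trend over gene span was argued against as well, since 98.1% of the genes stayed as low after it was removed. Tissue makeup may explain part, with a median of -1.07 over shared regions and 153 of 274 genes still that low there, which left it undecided. The 3 shared regions all held more UMIs of the smooth-muscle list than of the epithelial list, so epithelium-led tissue was not compared there. GC content could not be tested without a genome sequence. A response to wounding far from the wound and the capture area stay open, since the area was confounded with wounding.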

How the results depend on the processing

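The alternatives that leave out stray spots or the genes low in both wound libraries, the lists over regions centred per library and the profiles from the Plet1 region were chosen after the data were seen. The median log2 ratio of the neutrophil, cytokine, matrix-remodelling and smooth-muscle lists in KO over WT wound, and of the macrophage, collagen, MHC class II, complement, matrix-remodelling, T-cell and cytokine lists in WT wound over WT intact, stayed on the same side of random lists under every alternative that gave a value. Of the counts, shares and region ratios, 189 values stayed close to the reported one and 30 moved. Of the ratios of single named genes, 1275 stayed, 403 moved and 13 reversed. Of the core ratios, 12 stayed, 79 moved and 5 reversed, and of the genes within regions 42 stayed and 18 moved. The cause of the shifts was not tested, except that counts of genes followed the minimum of UMIs, which sets how many genes were compared. Each zero or low count limited what could be seen, as for Hgf and Cxcl2.

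For WT wound over WT intact, the 408 higher and 382 lower genes became 831 and 823 with at least 10 UMIs and 160 and 197 with at least 200. Over the 1 shared region they became 71, of which 22 were shared with the 408, and 125, of which 84 were shared with the 382. There the lists above random lists fell from 17 to 7 and those below from 6 to 1, and with centring per library 11 lay above. In the 1 region shared without centring, Clu was at 0.588, Spint2 at 0.992 and Ighg1 at 6.22 times the intact level, against directions the other way over whole libraries. In a shared region of the clustering centred per library, Clu was 9.59 times higher [7.32 to 12.8], as over whole libraries. With equal weight per spot Plat was at 0.945.

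For KO over WT wound, the 91 higher and 93 lower genes became 350 and 396 with at least 10 UMIs and 35 and 19 with at least 200. The lower genes became 154 with equal weight per spot and 60 over shared regions, and 5 lists lay below random lists by summed UMIs. Over shared regions Bglap was at 1.65, Spint1 at 0.887 and Mst1r at 0.982. With 1 tissue piece left out, the higher genes ranged from 89 to 150, the lower genes from 54 to 295 and the lists below from 5 to 9. Likewise Cfd ranged from 0.113 to 6.03, Car3 from 0.134 to 4.31, Slc9a3 from 0.233 to 2.68, Ankrd37 from 0.434 to 1.07, Retnla from 0.130 to 5.49 and Spint2 from 0.972 to 1.17. The region-standardised neutrophil ratio was 3.99 at resolution 1.0 and 4.31 with all variable genes, and the cytokine ratio 1.81 and 1.91, and 1.91 with centring. The share of neutrophil-rich KO spots was 5.42% at 0.2% of UMIs, 0% without S100a8 and S100a9, and 0.268% to 1.94% with 1 piece left out.

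Wound-associated epithelial genes, lower in the WT core than far from it, were higher at 1.40 with a core of cytokine genes and 1.84 with the Plet1 region. With that region smooth-muscle genes were at 0.761 in WT and 10.4 in KO, and by piece at 0.081 to 15.2 and 3.95 to 21.0. The tissue compared thus differed among pieces. In KO the wound-associated epithelial genes were 1.22 times higher in the core. They were at 0.792 with the top 5% of spots and ranged from 0.827 to 1.32 with 1 piece left out. All reported core ratios for macrophage, cytokine and collagen genes stayed above 1.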

Other observations

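The comparison of Krt5 with Krt14 was chosen after the result was seen, and the other tests before.

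Squamous keratin genes were counted at the wound. Krt14, a keratin of basal squamous epithelium, had 104 UMIs in WT wound, 137 in KO wound and 17 in WT intact, while Trp63, a regulator of such epithelium, had 0 in each. Of the KO UMIs of Krt14, 107 lay in piece 3, 23 in piece 2 and 7 in piece 1, against 40, 23 and 41 in WT wound pieces 1 to 3, so the KO count rested mostly on KO piece 3. In the region led by Arg1, Spp1 and Plet1 lay 81 of the Krt14 UMIs in WT wound and 110 in KO wound. Cell-cycle genes there were at 2.71 times the level of spots 5 or more steps away in WT and 5.54 times in KO. Antibody and B-cell genes were lower there, at 0.177 times the far level in WT and 0.047 times in KO.

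Anal or skin epithelium carried into the sections may be a source of Krt14. Of the 324 squamous UMIs of the wound libraries, mostly Krt14, 74.4% lay in that region, which held 11.5% of their spots, though such epithelium at the wound itself would give this share too. Krt5, the keratin that pairs with Krt14 in basal squamous cells, had 5 UMIs in WT and 0 in KO wound, or 2.07% of those of Krt14 [0.67 to 4.91], which argued against such epithelium as the whole source. Expression of Krt14 by colonic cells at the wound stays open.

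Cox8a and Cox5b, subunits of the last complex of the respiratory chain, were at 0.187 and 0.199 times the intact level in WT wound and at 0.168 and 0.188 in KO wound. Fewer respiratory chain transcripts in general might explain them, yet the other 79 nuclear genes of the chain had a median log2 ratio of -0.19 [-0.23 to -0.16], which argued against it. The bracket there came from resampling the genes as if independent.

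The spot with 811 Kap UMIs also held other kidney transcripts. Acsm2, a kidney acyl-CoA synthetase, had 24 UMIs on the spot and 0 in the KO pieces, Keg1 11 and 0, and Miox 6 and 0. A list of 20 kidney genes was 121.6 times higher on the spot than in the KO pieces [100.1 to 146.7], a value consistent with kidney RNA as a candidate source. Of the 20 genes, 14 had a UMI on the spot, and 3 had at least 50 UMIs in the KO pieces. The labels name no kidney sample, so how such RNA came there is open.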
